A study of Danio rerio with 12 samples.

How the data were processed

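RNA was measured in 12 sequencing libraries of zebrafish embryos, 3 for each of 4 groups: wild type (strain AB) and mycn mutant, each collected at 48 and at 72 hours post fertilization (hpf). Per the labels' protocols, embryos were kept in 0.3X Danieau buffer, total RNA was extracted with TRIzol and libraries were made by a standard Illumina procedure. The deposited values are raw counts of reads per Ensembl gene, with a gene symbol beside each identifier, and were not normalized. The submitters' processing notes name STAR, featureCounts, DESeq2 and the genome build GRCz11, with no versions and no roles. Strandedness, the annotation release, the allele of the mutant line, and whether a library came from single embryos, pools or separate clutches are not given in the sources used here. P-values therefore measure only the spread between these samples, which may be technical. Without known strand use, reads of overlapping or antisense genes cannot be told apart, and genes that share sequence with a near-identical copy are uncertain.

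The table held 31465 genes, 603 symbols stood on more than 1 of them, and every line named a gene. Library totals lay between 14793715 and 19732340 counts. A count of 3, used as the floor for a group at 0, was worth 0.151 to 0.216 CPM (counts relative to the library total, in the unit of edgeR) in a single library. Folds against a group with no counts were computed against 3 counts over the whole group and are lower bounds. Where a group held 1 to 3 counts, the ratio is given with its exact 95% counting interval. These intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No replicate pair held identical values, and every pair differed by more than sampling noise, with chi-square per degree of freedom from 4.14 to 49.7.

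Tests were run in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Genes were kept by filterByExpr with a minimum count of 10, which left 21068 genes. Libraries were scaled by TMM factors, and all 12 libraries entered 1 quasi-likelihood model (glmQLFit, glmQLFTest) with a coefficient per group, so that all groups shared 1 estimate of the spread. Contrasts were mutant against wild type at each age, the difference of these effects between 72 and 48 hpf, and 72 against 48 hpf in each genotype. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and a gene was called changed at an adjusted p under 0.05. Values of single genes are given as TMM-scaled CPM, mean ± SD over n = 3 libraries, and log2 fold changes come from the same model with their standard errors (SE). Unless another tool is named, every adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

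The model, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 37 lists covered Myc family members, ribosome and protein synthesis, cell cycle, stress responses, metabolism, and markers of gut, liver, pancreas and the other tissues that a whole embryo holds, and 1476 of 1554 listed symbols were found. Some genes stand on more than 1 list. Lists were tested against all other genes with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the 37 lists. Each list was also tested with its own estimated correlation, and with fry, which asks whether the genes of a list move, on balance, in 1 direction. Counts "adjusted over the list alone" repeat the adjustment within a list. Genes are named by this rule: mycn; the 10 largest rises and 10 largest falls among changed genes with average log2 CPM of at least 2, no overlap between the groups' libraries, and a symbol that is not a clone or locus name; up to 4 changed members of each list by smallest p, or the single member of smallest p where none changed; the 6 smallest p of the difference between ages; and 5 rises and 5 falls for each age contrast. Longer lists are not named in full, and genes named outside the rule are said to be so.

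The calling steps were tested on simulated counts drawn with the real means and library sizes, and with 1 spread per gene for all 4 groups. The real spread was larger at 48 than at 72 hpf, so recovery and false calls below hold only under a shared spread. For the 48 hpf comparison, run on 20841 genes, 21 of 67 genes changed 1.5-fold, 46 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered, with 7 false calls among 142. For 72 hpf, run on 20846 genes, these were 28 of 67, 51 of 67 and 62 of 66, with 9 false calls among 152. A list of ribosomal protein genes lowered by 0.3 on the log2 scale was called in both simulations, and 0 and 1 of the 36 lists left alone were called. Genes were drawn independently, so these counts do not show how often lists of correlated genes are called. The real ribosomal protein list had an estimated correlation of 0.493 at 48 hpf. When the 6 libraries of an age were split in other ways, up to 18 lists were called at 48 hpf and 15 at 72 hpf.

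Alternatives were DESeq2 size factors and library totals in place of TMM, no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, the DESeq2 1.42.0 Wald test, limma-voom, models of only the 6 libraries compared, and a minimum log2 fold change of 1. Leaving out the genes of the chromosome that carries mycn, and testing lists in models of 6 libraries, were added after seeing the data. Chromosomes and neighbouring genes came from a RefSeq gene table of assembly GRCz12tu, which is not the build of the counts, so no coordinates are given; 22021 of the 31465 genes and 19029 of the 21068 tested genes were matched by name. No genome sequence was used here.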

Results

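Transcripts were counted in 12 libraries of RNA from zebrafish embryos: 3 libraries each of wild-type and mycn mutant embryos at 48 hpf, and 3 of each at 72 hpf. mycn encodes a transcription factor of the Myc family, and loss of function of its human counterpart MYCN is known to cause Feingold syndrome 1, in which the gut can be malformed. The series title names intestinal development and the making of ribosomes as its subject. The comparisons therefore ask which genes differ between mutant and wild-type embryos at each age. Library totals ran from 14793715 counts (mutant 72 hpf replicate 3) to 19732340 (wild-type 48 hpf replicate 3). The first principal component of the log2 CPM values held 84.1% of the variance and separated the ages, and the second held 3.75%. Replicates varied most at 48 hpf: the biological coefficient of variation within groups was 0.200 in wild-type and 0.136 in mutant libraries at 48 hpf, against 0.0704 and 0.0848 at 72 hpf.

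mycn itself (ENSDARG00000006837) was measured first, because it checks the labels. Its RNA was higher, not lower, in the mutant libraries at both ages. At 48 hpf it stood at 74.0 ± 14.9 CPM in wild-type and 222 ± 25.2 CPM in mutant libraries (SD, n = 3 each; log2 fold change 1.59, SE 0.13, adjusted p = 5.45e-06). At 72 hpf it stood at 77.3 ± 2.25 and 153 ± 9.87 CPM (log2 fold change 0.98, SE 0.13, adjusted p = 0.00144). The lowest mutant library lay above the highest wild-type library at both ages, with 203 against 90.1 CPM at 48 hpf and 141 against 79.8 CPM at 72 hpf. The rise did not differ detectably between the ages (adjusted p of the difference = 0.192). The labels do not describe the allele, so a level of RNA cannot show how much functional protein was made. Because the measured direction goes against what loss of a transcript would give, these libraries are called mutant-labelled from here on, and every direction below rests on the labels.

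**Figure D1:**
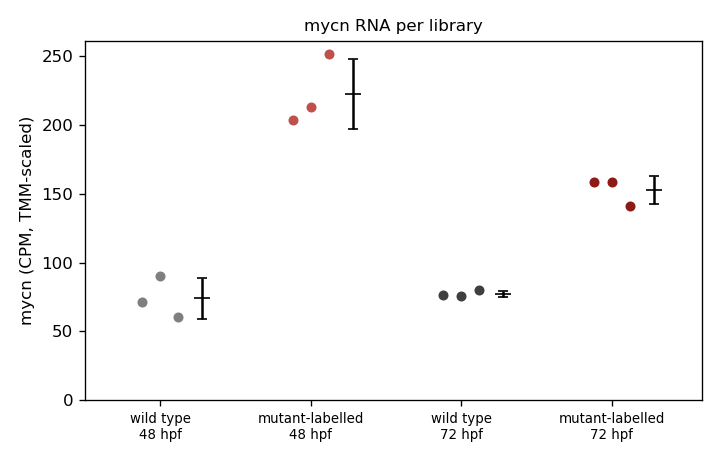
mycn RNA in each of the 12 libraries, in TMM-scaled CPM (vertical axis, from 0), by genotype label and age (horizontal axis). Points are libraries and the bar beside them is the mean ± SD of 3; all 6 mutant-labelled libraries lie above all 6 wild-type libraries, with means of 222 against 74.0 CPM at 48 hpf and 153 against 77.3 CPM at 72 hpf.

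At 48 hpf, genes of cytosolic ribosomal proteins were lower in the mutant-labelled libraries, and the other lists of protein synthesis had smaller medians in either direction. The 80 measured proteins of the cytosolic ribosome had a median log2 fold change of -0.35, and 79 of the 80 had a negative value. Of these, 19 fell and 0 rose in edgeR over all genes, and 72 fell when adjusted over the list alone. At an unadjusted p under 0.05, in DESeq2 and in limma-voom 0 rose as well, and 73, 53 and 36 fell. An edgeR model of only the 6 libraries of this age called 0 of the 80 lower, with 73 lower at an unadjusted p under 0.05, and the list kept its median of -0.35. rpl12 fell from 2366 ± 57.7 to 1680 ± 92.4 CPM (log2 fold change -0.49, SE 0.10, adjusted p = 0.0132), and rps20, rpl18 and rps6 fell by 0.47, 0.41 and 0.45 on the log2 scale (adjusted p = 0.0243, 0.0247 and 0.0253). Among 132 genes of ribosome biogenesis and the nucleolus the median was -0.12. Of these, 6 fell, and 6 also when adjusted over the list alone. As the mean over the list of log2 CPM centred per gene, the genotypes overlapped, with wild-type replicates at 0.17, 0.17 and 0.08 and mutant-labelled ones at 0.13, 0.06 and -0.18. ddx21, a nucleolar RNA helicase, fell from 179 ± 14.5 to 93.4 ± 7.90 CPM (log2 fold change -0.94, SE 0.10, adjusted p = 1.78e-04). The assembly factors pno1, nop53 and riok1 fell by 0.61, 0.75 and 0.53 on the log2 scale (adjusted p = 0.002, 0.00514 and 0.0262). Of 47 translation factors 7 fell and 2 rose, or 16 and 4 adjusted over the list alone, and 0 passed in the model of only the 6 libraries. eef1a1l1, which carries aminoacyl-tRNA to the ribosome, fell from 13092 ± 220 to 8774 ± 767 CPM (log2 fold change -0.58, SE 0.11, adjusted p = 0.00899). The helicase gene eif4a1a rose by 0.69 (adjusted p = 0.0192). The ribosomal protein list, ribosome biogenesis and translation factors were lower than other genes in camera (adjusted p = 6.52e-31, 2.82e-05 and 2.14e-04). Each call was lost with an estimated correlation (adjusted p = 0.357, 0.62 and 0.429). Of these lists fry called only the ribosomal proteins (adjusted p = 0.0253, against 0.193 and 0.0635). RNA polymerase III subunits were at the threshold (median -0.15, adjusted p = 0.049, and adjusted p = 0.357 with an estimated correlation). DESeq2 size factors and library totals also ended this call (adjusted p = 0.0511 and 0.065). tRNA synthetases had a median of 0.09 (adjusted p = 0.0388, and adjusted p = 0.609 with an estimated correlation). No member passed in edgeR, DESeq2 or limma-voom, and 4 were higher and 1 lower at an unadjusted p under 0.05. Mitochondrial ribosomal proteins had a median of 0.03 (adjusted p = 0.539).

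Genes of nucleotide synthesis fell singly rather than as a list. Of 42 members 4 fell, and 5 when adjusted over the list alone. ppat, the first enzyme of purine synthesis, fell from 69.3 ± 3.19 to 41.7 ± 3.34 CPM (log2 fold change -0.73, SE 0.09, adjusted p = 5.67e-04). cad, which starts pyrimidine synthesis, fell by 0.68 and impdh1b, of guanine nucleotide synthesis, by 0.69 on the log2 scale (adjusted p = 0.00228 and 0.00166). ppat and cad lie on the chromosome that carries mycn. The list had a median of -0.07 (adjusted p = 0.0689), which turned to 0.02 under library totals alone. Chaperone genes moved both ways. hspa8 fell from 4230 ± 547 to 2457 ± 136 CPM (log2 fold change -0.78, SE 0.12, adjusted p = 0.00211). hsp90aa1.1, on the chromosome of mycn, rose by 0.90 (adjusted p = 0.0282).

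Markers of several tissues also differed at 48 hpf. Pigment cell genes had a median of -0.36, with 3 of 25 lower and 9 adjusted over the list alone. gpnmb fell from 94.1 ± 20.2 to 45.8 ± 6.12 CPM (log2 fold change -1.04, SE 0.14, adjusted p = 9.53e-04) and pnp4a, a marker of iridophores, by 0.74 on the log2 scale (adjusted p = 0.00868). Of 65 hepatocyte genes 8 fell, and 13 adjusted over the list alone (median -0.26). f10, coagulation factor X, fell from 67.8 ± 19.9 to 33.8 ± 3.76 CPM (log2 fold change -1.01, SE 0.16, adjusted p = 0.00319), and uox, urate oxidase, by 1.43 on the log2 scale (adjusted p = 0.00797). Among 26 erythroid genes hbbe1.1, an embryonic globin, fell from 6298 ± 1554 to 1595 ± 688 CPM (log2 fold change -1.98, SE 0.25, adjusted p = 6.13e-04), and the list median was -0.10. In the other direction, 2 of 39 lens genes rose, or 12 adjusted over the list alone (median 0.48). crygmx rose by 0.80 and lim2.5 by 1.15 on the log2 scale (adjusted p = 0.0391 and 0.0197). Of 40 genes of differentiated neurons 4 rose, or 10 adjusted over the list alone (median 0.26). They were tuba1c and the intermediate filament genes nefma, nefmb and inab, higher by 0.49 to 0.76 (adjusted p = 0.0218 to 0.0496). In cholesterol synthesis 2 of 28 rose, or 9 adjusted over the list alone (median 0.38). hmgcra, the rate-limiting reductase, rose from 2.90 ± 0.536 to 7.25 ± 1.61 CPM (log2 fold change 1.32, SE 0.19, adjusted p = 0.002), and fdps by 0.64 (adjusted p = 0.00419). Of 58 mitotic genes 2 rose, cenpf and fbxo5, or 9 adjusted over the list alone (median 0.22). In a model of only the 6 libraries of this age, 0 lens, neuron, cholesterol or mitosis genes passed. There 1 pigment, 1 hepatocyte and 1 erythroid gene fell and 0 rose.

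Library values overlapped between the genotypes in several of these lists. On the same scale as for ribosome biogenesis, hepatocyte genes stood at 0.25, -0.31 and 0.45 in wild-type replicates 1 to 3 and at -0.21, -0.01 and -0.41 in the mutant-labelled ones, so wild-type replicate 2 lay below 2 mutant-labelled libraries. Lens genes stood at -1.59, -0.78 and -1.01 against -0.57, -0.42 and -1.01, and neuron genes at -1.46, -1.41 and -1.06 against -0.81, -1.0 and -1.30. Of the 16 lists called at this age 9 overlapped in this way, and 7 did not, among them ribosomal proteins, pigment cells and cholesterol synthesis.

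In camera the pigment, hepatocyte, lens, neuron, cholesterol and mitosis lists passed at 48 hpf (adjusted p = 6.27e-08, 4.92e-07, 1.41e-08, 2.64e-08, 2.44e-06 and 1.41e-08). With an estimated correlation none of them did (adjusted p = 0.357, 0.567, 0.429, 0.429, 0.357 and 0.429). Smaller shifts were called for neural progenitors (median 0.12, adjusted p = 0.00245), circadian clock genes (median -0.11, adjusted p = 0.00711), endoderm transcription factors (median -0.13, adjusted p = 0.024), erythroid genes (adjusted p = 0.0388) and epidermis and ionocytes (median -0.11, adjusted p = 0.0393). These were also lost with an estimated correlation (adjusted p = 0.429, 0.429, 0.429, 0.692 and 0.609), and the epidermis call ended under library totals (adjusted p = 0.058). Without wild-type 48 hpf replicate 1 the erythroid median was 0.04. Of the 57 enterocyte genes 6 fell and 2 rose, or 9 and 2 adjusted over the list alone. alpi.2, an intestinal alkaline phosphatase, fell from 1.89 ± 1.14 to 0.192 ± 0.0498 CPM, and cdx1b, a gut transcription factor, from 2.82 ± 0.510 to 1.21 ± 0.341 CPM (adjusted p = 0.00455 and 0.00946). The enterocyte list did not pass (median -0.11, adjusted p = 0.0969), though library totals brought it past the threshold (adjusted p = 0.0239).

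The largest single falls at 48 hpf included a copy of dap1b (ENSDARG00000109678), with 1047 counts over the wild-type and 0 over the mutant-labelled libraries, at least 331-fold lower (adjusted p = 5.11e-08). A second gene with the symbol dap1b held 71.8 ± 9.99 CPM in wild-type and 67.2 ± 8.44 CPM in mutant-labelled libraries, and the sum of both 93.3 ± 11.1 and 67.2 ± 8.44 CPM. The second copy thus did not gain what the first lost. mgst2, a microsomal glutathione transferase, fell from 34.1 ± 2.89 to 5.71 ± 0.529 CPM (log2 fold change -2.57, SE 0.14, adjusted p = 5.11e-08). znf1156 fell from 18.3 ± 2.38 to 3.05 ± 1.47 CPM (log2 fold change -2.58, SE 0.26, adjusted p = 6.67e-05). myrfl, gc (the vitamin D binding protein), zanl, LO017829.1, ITLN1 (1 of many), prnpa and agt (angiotensinogen) also fell, by 2.07 to 4.54 on the log2 scale. Besides mycn and hmgcra, rises included soul5, from 7.77 ± 2.80 to 21.4 ± 7.55 CPM, and crtac1a, from 4.77 ± 0.988 to 11.7 ± 3.01 CPM (adjusted p = 0.0123 and 0.00551). slc1a2a and slc6a19a.2 also passed as rises, from 1 and 2 to 12 and 20 counts over the groups, ratios of 12.7 (95% counting interval 1.87 to 541) and 10.6 (2.56 to 93.1). The photoreceptor kinase gene grk1b, pdca and the glutamate receptor gene grm8b rose below 2 CPM.

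In all, 641 of 21068 tested genes changed at 48 hpf, 219 higher and 422 lower (edgeR quasi-likelihood test, adjusted p under 0.05). At this age 16 of 37 lists were called, 0 of them with an estimated correlation. Of the 10 splits of these 6 libraries into groups of 3, 6 called as many lists, the real split included. The count of genes was 222 and 323 without mutant-labelled 48 hpf replicates 1 and 2. Without wild-type 48 hpf replicate 3 it was 1133, and without any other library 436 to 935. With library totals alone 740 genes passed, 453 higher and 287 lower, and the median of all genes moved to 0.09 on the log2 scale. When only the 6 libraries of this age were fitted, 74 genes passed, all of them among the 641, and of the 73 named changed genes other than mycn 68 were tested there and 58 of these lost their call. The genes dap1b, mgst2, znf1156, ddx21, ppat, hspa8, pck1, cyp2ad3, hbbe1.1 and gpnmb kept it in every alternative that tested them.

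At 72 hpf, genes of the intestine were lower in the mutant-labelled libraries. The median of 57 enterocyte genes was -0.43. Of these, 12 fell and 0 rose in edgeR, and 22 fell when adjusted over the list alone. DESeq2 and limma-voom called 18 and 16 lower and 0 higher, and at an unadjusted p under 0.05 29 were lower and 2 higher. cldn15la, a claudin of gut epithelium, fell from 54.2 ± 3.07 to 21.9 ± 0.593 CPM (SD, n = 3 each; log2 fold change -1.3, SE 0.13, adjusted p = 3.76e-04). anpepb, a brush border aminopeptidase, fell from 50.3 ± 7.33 to 21.5 ± 1.27 CPM (log2 fold change -1.22, SE 0.13, adjusted p = 6.97e-04). fabp6, which binds bile acids in the ileum, fell from 15.7 ± 4.84 to 4.19 ± 1.05 CPM (log2 fold change -1.90, SE 0.25, adjusted p = 0.00273). Transcription factors of the endoderm fell with them, 3 of 28 over all genes and 7 adjusted over the list alone (median -0.30). cdx1b fell from 31.9 ± 1.72 to 14.3 ± 1.86 CPM (log2 fold change -1.16, SE 0.14, adjusted p = 7.80e-04), cdx1a by 1.3 and elf3 by 0.64 on the log2 scale (adjusted p = 0.0116 and 0.044).

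The enterocyte and endoderm lists were lower than other genes in camera (adjusted p = 6.21e-29 and 4.66e-09). They were the only 2 of the 37 lists at this age that also passed with an estimated correlation (adjusted p = 0.025 and 0.0316). The lists share cdx1b. With DESeq2 size factors and with library totals the enterocyte median was -0.43 and -0.45. Other gut genes among the largest falls were s100a10a, from 44.9 ± 1.83 to 18.4 ± 2.39 CPM, and the mucin gene muc13b, from 21.9 ± 2.04 to 9.22 ± 0.616 CPM (adjusted p = 0.00109 and 0.0156). insl5a, a hormone gene of gut endocrine cells, fell by 2.37 on the log2 scale (adjusted p = 0.0292). It was the single change among 27 endocrine genes, whose median was 0.03 although the mean was -0.19 (adjusted p = 0.125). muc5.2, on the list of goblet and secretory cells, rose by 0.75 (adjusted p = 0.0101). That list as a whole was lower, with 8 of 10 members negative (median -0.24, adjusted p = 0.0259, and adjusted p = 0.181 with an estimated correlation).

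**Figure D2:**
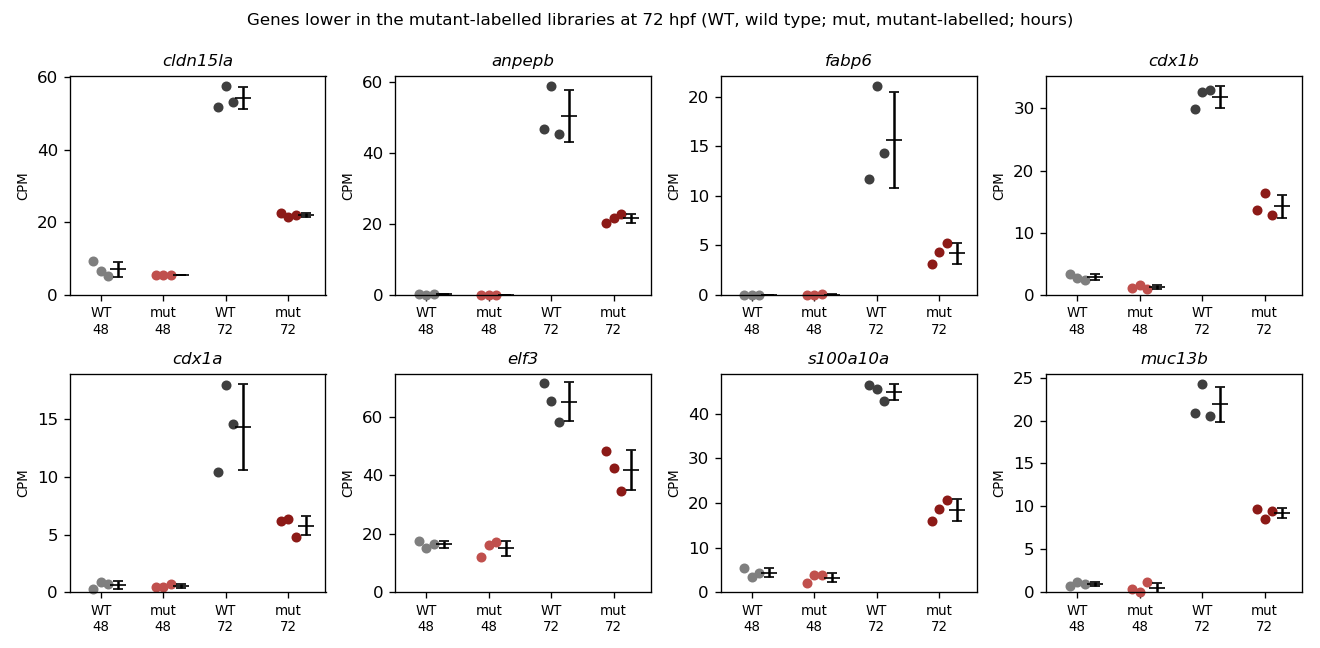
Expression of 8 genes that fell at 72 hpf, in TMM-scaled CPM (vertical axes, each from 0), by genotype and age (horizontal axes; WT, wild type; mut, mutant-labelled; ages in hpf). Points are libraries and bars the mean ± SD of 3; at 72 hpf each gene's 3 mutant-labelled libraries lie below its 3 wild-type libraries, as for cldn15la at 21.9 against 54.2 CPM.

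Ribosomal protein genes were lower at 72 hpf too. Their median log2 fold change was -0.31 and 78 of the 80 had a negative value, and 2 fell over all genes against 63 adjusted over the list alone. They were rps23, from 446 ± 38.6 to 325 ± 15.9 CPM, and rps14, from 852 ± 48.5 to 614 ± 28.4 CPM (adjusted p = 0.044 and 0.0472). With only the 6 libraries of this age 31 of the 80 fell. camera called the list (adjusted p = 4.11e-44), with adjusted p = 0.153 under an estimated correlation, and fry called it (adjusted p = 0.0253). Exocrine pancreas genes had negative values in 22 of 22 members (median -0.38, adjusted p = 6.07e-09, and adjusted p = 0.153 with an estimated correlation). None passed in edgeR over all genes, while 8 were lower at an unadjusted p under 0.05, 4 adjusted over the list alone, and 1 each in DESeq2 and limma-voom. The smallest p was that of prss59.1, at 33.9 ± 3.26 and 21.5 ± 5.0 CPM (adjusted p = 0.0994). Hepatocyte genes stood higher at this age. Of 65, 2 rose, or 3 against 1 lower adjusted over the list alone (median 0.22, adjusted p = 8.75e-07, and adjusted p = 0.632 with an estimated correlation). They were agxtb, by 0.61, and cyp2ad3, on the chromosome of mycn, by 0.56 (adjusted p = 0.0155 and 0.0148). Of 39 collagen and matrix genes the actinodins and1 and and2 rose, or 4 adjusted over the list alone (median 0.25, adjusted p = 2.64e-11, and adjusted p = 0.282 with an estimated correlation). and1 went from 79.9 ± 6.90 to 129 ± 13.4 CPM (adjusted p = 0.0254). Photoreceptor genes had a median of 0.26 (adjusted p = 1.39e-11, and adjusted p = 0.105 with an estimated correlation). Of 36 members 0 passed in edgeR over all genes, 9 were higher adjusted over the list alone, 11 at an unadjusted p under 0.05, 7 in DESeq2 and 2 in limma-voom. Skeletal muscle genes had a median of 0.24 (adjusted p = 4.76e-07, and adjusted p = 0.588 with an estimated correlation). Of 54 members 0 passed in edgeR with all 12 libraries, DESeq2 or limma-voom, and 8 were higher and 1 lower at an unadjusted p under 0.05. With only the 6 libraries of this age, edgeR called 11 muscle, 10 photoreceptor, 10 collagen and 10 hepatocyte genes higher. It also called 7 exocrine pancreas genes and 2 hepatocyte genes lower, and 0 others of these lists against their list's direction. Of the 16 lists called at this age 5 overlapped between the genotypes in their library values, among them exocrine pancreas and hepatocytes.

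Smaller list shifts at 72 hpf were called by camera for neurons (median 0.12, adjusted p = 0.00155) and, downward, for translation factors (-0.10, adjusted p = 0.0016), mitosis (-0.08, adjusted p = 0.00251), pigment cells (-0.09, adjusted p = 0.00641), cholesterol synthesis (-0.09, adjusted p = 0.00791), interferon and complement defence (-0.19, adjusted p = 0.0145) and ribosome biogenesis (-0.04, adjusted p = 0.0176). With an estimated correlation these stood at adjusted p = 0.724, 0.588, 0.724, 0.588, 0.562, 0.28 and 0.724. Not called at either age were the Myc family, mitochondrial ribosomal proteins, nucleotide synthesis, DNA replication, p53 targets, the unfolded protein response, heat shock, endocrine cells, cardiac muscle, neutrophils and macrophages, cartilage and bone, pronephros, vessels and glycolysis. p53 target genes had medians of -0.01 and 0.05 (adjusted p = 0.592 and 0.57). DNA replication genes had medians of 0.04 and -0.06 (adjusted p = 0.399 and 0.136).

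The largest rise at 72 hpf was cyp2p9, from 3.34 ± 0.813 to 17.3 ± 1.6 CPM (log2 fold change 2.37, SE 0.27, adjusted p = 5.84e-04). ociad2 fell from 23.6 ± 1.96 to 9.21 ± 0.614 CPM (log2 fold change -1.36, SE 0.12, adjusted p = 8.92e-05). Both lie on the chromosome that carries mycn, as does cep57l1, which rose by 0.88. rrm2, a subunit of ribonucleotide reductase, stood on a pair of identifiers that moved in opposite directions. ENSDARG00000020711 fell from 49.5 ± 1.6 to 19.96 ± 2.04 CPM and ENSDARG00000078069 rose from 16.5 ± 1.99 to 43.9 ± 4.70 CPM. Their sum was 66.0 ± 3.17 and 63.9 ± 6.74 CPM, so the assignment of reads between the copies leaves both changes uncertain. gck, glucokinase, rose from 4.93 ± 0.784 to 11.7 ± 1.89 CPM (adjusted p = 0.0103), and bicd2, ankrd1b, nmrk2 and igfn1.3 rose by 0.69 to 1.16 on the log2 scale. cyp2y3, tmem176l.2 and abcb11a, a bile salt pump gene, fell by 1.23 to 1.84.

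In all, 117 genes changed at 72 hpf, 28 higher and 89 lower, and 16 of 37 lists were called. The count rested on each library of this age. It was 24 without wild-type replicate 2, 28 without mutant-labelled replicate 3, 40 to 48 without any other 72 hpf library, and 195 and 193 without wild-type 48 hpf replicates 3 and 2. With only the 6 libraries of 72 hpf fitted, 793 genes passed, 329 higher and 464 lower, the 117 among them, and 26 of 57 enterocyte genes fell and 2 rose. Of 33 named changes at this age other than mycn, 24 lost their call in at least 1 alternative. cdx1a lost it in 5 of 20 alternatives, elf3 in 8, and rps23 and rps14 in 10 each. The 9 kept everywhere were anpepb, cdx1b, cldn15la, cyp2p9, fabp6, ociad2, s100a10a, tmem176l.2 and 1 copy of rrm2.

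The effects at the 2 ages were then compared. Both ages shared 17 changed genes, and 14 of these moved in the same direction. They were 4 higher (0.291 expected from independent lists, Fisher's exact p = 1.91e-04) and 10 lower (1.78 expected, Fisher's exact p = 1.16e-05). Both tests treat genes as independent replicates, which they are not. Of the 4 higher ones 3 were mycn itself and rock2b and cep57l1, which are among the 100 tested genes nearest to it, as is BX279523.1 of the 10 lower ones. Of the other 13 shared genes 10 moved in the same direction, 1 higher and 9 lower. cdx1b and pnp4a were lower at both ages, while cyp2ad3, gmds and slc6a19a.2 moved in opposite directions. These comparisons share no library. Across all 21068 genes the log2 fold changes at 48 and 72 hpf were weakly related (Pearson r = 0.0649, Spearman rho = 0.124), and genes are not independent replicates. Pearson r was 0.184 among genes with average log2 CPM of at least 3, 0.00567 without a low-count filter, and 0.0259, 0.0338, 0.0409 and 0.0415 without mutant-labelled 48 hpf replicate 1, wild-type 72 hpf replicate 1, mutant-labelled 72 hpf replicate 2 and wild-type 72 hpf replicate 2.

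A test of the difference itself passed for 99 genes, 60 with a higher effect at 72 hpf and 39 with a lower one. mgst2 stood at 34.1 and 5.71 CPM at 48 hpf but at 6.48 and 5.71 CPM at 72 hpf, in wild-type and mutant-labelled libraries (difference of log2 fold changes 2.39, SE 0.20, adjusted p = 5.71e-05). tmem176l.3a stood at 22.3 and 5.72, then 6.42 and 6.61 CPM (2.01, SE 0.22, adjusted p = 6.87e-04). In both genes the wild-type 48 hpf libraries alone stood apart from the other groups. cyp2ad3, gmds and tnfaip2a, all on the chromosome of mycn, and ppm1h differed by 1.31, -1.22, 1.3 and 1.57 (adjusted p = 6.87e-04, 0.00275, 0.00281 and 0.00296). Of 65 hepatocyte genes 5 had a higher effect at 72 hpf, or 13 adjusted over the list alone (median difference 0.53, adjusted p = 1.72e-14, and adjusted p = 0.466 with an estimated correlation). Cholesterol synthesis went the other way, 1 gene over all genes and 11 adjusted over the list alone (median difference -0.44, adjusted p = 2.93e-10, and adjusted p = 0.182 with an estimated correlation). The ribosomal protein list did not differ detectably between ages (median difference 0.05, adjusted p = 0.405), nor did enterocytes (-0.18, adjusted p = 0.0628) or endoderm transcription factors (-0.10, adjusted p = 0.479). Of the 37 lists 13 were called, 0 of them with an estimated correlation, and 50 of 100 splits of the libraries called as many. The count of 99 genes became 23 without wild-type 72 hpf replicate 2 and 276 without wild-type 48 hpf replicate 2, and library totals turned its balance to 43 higher and 73 lower.

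**Figure D3:**
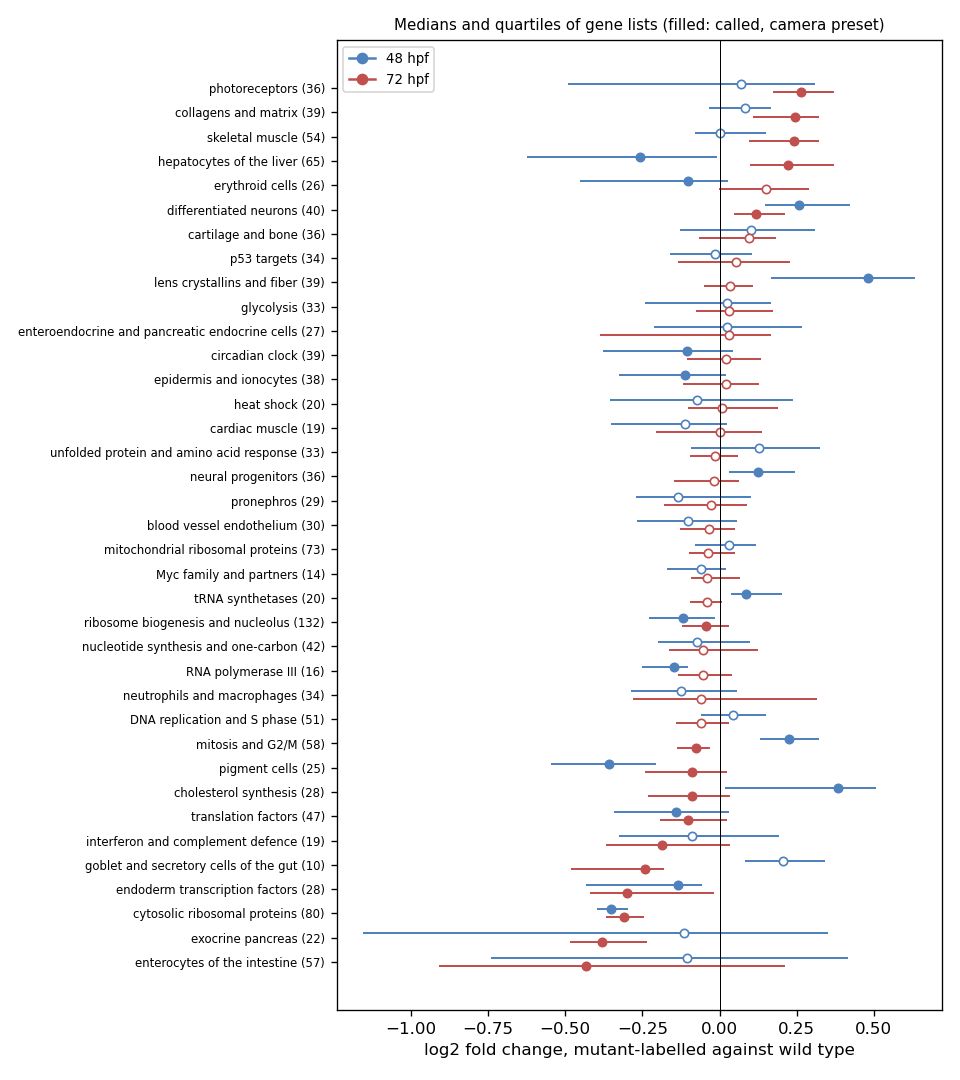
Medians (points) and quartiles (lines) of the log2 fold change, mutant-labelled against wild type (horizontal axis), over the tested members of each of 37 gene lists (vertical axis, number of members in parentheses) at 48 and 72 hpf. Filled points mark lists called by camera at its preset correlation; enterocytes lie at -0.43 at 72 hpf and ribosomal proteins at -0.35 and -0.31. Under library totals alone, medians of the Myc family, nucleotide synthesis, p53 and heat shock lists at 48 hpf, and of heat shock and cardiac muscle at 72 hpf, change sign.

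Between 48 and 72 hpf most of the transcriptome changed in both genotypes. In wild-type libraries 14918 genes changed (7450 higher, 7468 lower) and in mutant-labelled libraries 14785 (7528 higher, 7257 lower). Of 36 photoreceptor genes 35 rose in each genotype, with medians of 5.72 and 5.49 on the log2 scale. opn1sw1, the ultraviolet cone opsin, went from 2 to 119246 counts over the wild-type libraries, a ratio of 51605 (95% counting interval 14286 to 426128). The photoreceptor genes opn1mw1, gnb3b and prph2a also rose (adjusted p of 6.92e-14 or less in the genotype that named each). Of 22 exocrine pancreas genes 21 rose in wild-type and 20 in mutant-labelled libraries. ctrl was at least 392-fold higher in wild type and prss59.2 at least 1612-fold higher in the mutant-labelled group. Of 57 enterocyte genes 35 and 34 rose and 18 and 17 fell. fabp6 was at least 252-fold higher in wild type and anpepb at least 330-fold higher in the mutant-labelled group. Of 80 ribosomal protein genes 77 fell in each genotype (medians -1.28 and -1.29). Of 26 erythroid genes 25 and 24 fell (medians -4.14 and -3.35), among them the globin hbbe3, from 979 ± 317 to 0.534 ± 0.505 CPM in wild type. The hatching enzyme genes he1.1 and he1.2 fell by 9.35 and 9.92 on the log2 scale in wild type. ctslb was at least 598-fold lower there and at least 560-fold lower in the mutant-labelled group. The dap1b copy fell in wild type and dao.1 fell by 7.03 in the mutant-labelled group. With library totals alone the median of all genes rose by 0.41 on the log2 scale in wild type and by 0.32 in the mutant-labelled group, so directions here are relative to the average gene. Then 10466 genes were higher and 4658 lower in wild type, and 9691 and 5027 in the mutant-labelled group.

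Across genes, the genotype effect at 48 hpf followed the wild-type change with age weakly, with a slope of 0.0795. Both sides share the wild-type 48 hpf libraries, and simulated groups without an effect gave 0.0185 ± 0.0024 (SD, 20 simulations), a spread that leaves out variation shared by many genes of a library. The simulations gave all groups 1 spread per gene. The real coefficient of variation was 0.200 in wild-type 48 hpf and 0.0704 in wild-type 72 hpf libraries. Simulated values are therefore likely too small at 48 hpf and too large in size at 72 hpf, and settle neither age. Over libraries left out in turn the slope had a standard error of 0.0461, so its excess over the simulated value is less than 2 such errors. The covariance was 0.226 against 0.0557 ± 0.00728. Those 3 libraries are too few to be split, so part of the excess may come from sharing them, and without wild-type 48 hpf replicate 3 the slope was 0.134. At 72 hpf the slope was -0.0149 (standard error over libraries 0.0184) against a simulated -0.0133 ± 0.00164, and the covariance -0.0424 against -0.0399 ± 0.00503. Most lists called at 48 hpf had medians with the sign of their wild-type age medians. Pigment cells had -0.36 and -1.91, hepatocytes -0.26 and -0.89, neurons 0.26 and 2.31, and lens 0.48 and 2.08. Mitosis (0.22 and -0.70), circadian clock, neural progenitors, endoderm transcription factors and RNA polymerase III went the other way. Both medians use the wild-type 48 hpf libraries. A difference in stage between the 48 hpf groups was not tested.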

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

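The results here are those whose genotype effect differed between 72 and 48 hpf in the planned test of that difference; they comprise 24 named genes and 13 gene lists. Values are the effect at 72 hpf minus the effect at 48 hpf on the log2 scale, mutant-labelled against wild type, so a positive value means a higher effect at 72 hpf. No group held enough libraries for a test of single outlying libraries.

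Among hepatocyte genes, uox (1.85), f10 (1.38), cyp2ad3 (1.31) and hpda (1.2) had higher effects at 72 hpf, and the list median was 0.53. The hepatocyte values of single libraries overlapped between the genotypes at both ages. The gluconeogenesis genes pck1 and g6pca.1, placed on the enterocyte and endocrine lists, moved the same way, by 1.19 and 1.2. hbbe1.1, an embryonic globin, differed by 2.12 and the erythroid list by 0.36. ca15a, a carbonic anhydrase of ionocytes, differed by 1.18. The nucleolar helicase ddx21 differed by 0.68.

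mgst2 (2.39), tmem176l.3a (2.01), znf1156 (2.35), prnpa (2.86) and ppm1h (1.57) had higher effects at 72 hpf. For mgst2 and tmem176l.3a the wild-type 48 hpf libraries alone stood apart, at 34.1 CPM against 5.71, 6.48 and 5.71 and at 22.3 against 5.72, 6.42 and 6.61 in the other groups, so the difference is not a recovery of the mutant-labelled libraries. ppm1h was low in the mutant-labelled 48 hpf libraries alone, at 5.87 CPM against 17.9, 19.7 and 19.3. On the chromosome of mycn, cyp2p9 (2.27) and tnfaip2a (1.3) had higher effects at 72 hpf, and ociad2 (-1.02), gmds (-1.22), pdia6 (-0.83) and actc1a (-2.16) lower ones. hmgcra (-1.41), mmp9 (-1.58) and the rrm2 copy ENSDARG00000020711 (-1.3) also had lower effects at 72 hpf. slc6a19a.2 gave -4.34, a fitted value that rests on 2 counts in the wild-type 48 hpf libraries and is no bound.

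Lists with a lower effect at 72 hpf were lens (median -0.46), cholesterol synthesis (-0.44), goblet and secretory cells (-0.42), mitosis (-0.35), neural progenitors (-0.21), neurons (-0.14) and tRNA synthetases (-0.12). Lists with a higher one were, besides hepatocytes and erythroid cells, skeletal muscle (0.24), pigment cells (0.23), the circadian clock (0.19) and collagens (0.15). None of the 13 list calls held in camera with an estimated correlation, where 0 lists passed after adjustment, and fry called 2, goblet and secretory cells and cholesterol synthesis (adjusted p = 0.0404 for both).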

How the results depend on the processing

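Leaving out the chromosome of mycn, and testing lists in models of 6 libraries, were chosen after seeing the data. All other alternatives were planned. mycn kept its direction and its call in every alternative, from 1.47 to 1.75 at 48 hpf and from 0.95 to 1.03 at 72 hpf when each library was left out in turn (highest adjusted p = 5.29e-05 and 0.0191). Of 132 calls of named genes, in which a gene named in several comparisons counts once for each, 87 were lost in at least 1 alternative, 45 in none, and 0 reversed. Of 32 list calls at 48 and 72 hpf 30 were lost in some alternative, mostly the estimated correlation, and 2 in none.

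Counts below are for 48 hpf, 72 hpf and the difference between ages. The DESeq2 Wald test called 1023, 249 and 253 genes, limma-voom 597, 195 and 93, and no low-count filter 855, 154 and 175. Models of only the 6 libraries gave 74 and 793. The spread between replicates was larger at 48 hpf than at 72 hpf (biological coefficient of variation 0.168 and 0.0777 in these models), and a shared estimate averages both. P-values of the shared model therefore tend to be too small at 48 hpf and too large at 72 hpf. Its counts of 641 and 117 genes do not show which age changed more. A minimum 2-fold change left 274 and 51 genes, and 8597 and 8374 for the age change in wild-type and mutant-labelled groups, by construction. Without the chromosome of mycn 593, 78 and 72 genes passed, and 15 and 16 lists. P-values of genes were adjusted again over the remaining ones, which ended further calls on other chromosomes. At 72 hpf only mycn, 6 of its 100 nearest genes and 11 on the rest of its chromosome had been called. Lists called fell from 16, 16 and 13 to 0, 2 and 0 with an estimated correlation (4 lists at 48 hpf had an unadjusted p under the threshold), and fry called 4, 3 and 2. At 48 hpf fry called ribosomal proteins, RNA polymerase III, pigment cells and cholesterol synthesis. At 72 hpf it called ribosomal proteins, enterocytes and endoderm transcription factors. The correlation between ages was 0.00567 without a filter and 0.184 among genes with average log2 CPM of at least 3, and the slopes on the age change were 0.191 and -0.0873 without a filter; the cause was not tested.

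The replicate number as a block gave 438, 74 and 59 genes. Residuals of libraries with the same number and age correlated between -0.155 and 0.0233, and 2 of 12 libraries matched best with their own number. No pairing by number was thus detected, which does not exclude one with 3 libraries per group.

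Leaving out each library in turn gave 222 to 1133 genes at 48 hpf, 24 to 195 at 72 hpf and 23 to 276 for the difference. For the age change it gave 13981 to 15211 genes in wild-type and 13851 to 15269 in mutant-labelled libraries, and for lists 14 to 18, 14 to 19 and 9 to 18. At 48 hpf the count was 222 and 323 without mutant-labelled 48 hpf replicates 1 and 2, and 1133 without wild-type 48 hpf replicate 3. For the difference it was 276 and 264 without wild-type 48 hpf replicates 2 and 3, 54 and 51 without mutant-labelled 48 hpf replicates 1 and 2, 47, 23 and 37 without wild-type 72 hpf replicates 1 to 3, and 43, 37 and 24 without the mutant-labelled ones. The correlation between ages lay between 0.0259 (without mutant-labelled 48 hpf replicate 1) and 0.0659, the slope at 48 hpf between 0.0794 and 0.134, and that at 72 hpf between -0.0350 (without wild-type 72 hpf replicate 1) and -0.0128. The erythroid list at 48 hpf reversed, from a median of -0.10 to 0.0425, without wild-type 48 hpf replicate 1, and stood at -0.314 without wild-type 48 hpf replicate 3. The cause of these shifts was not tested.

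The spread and the depth both limit the smallest changes. In the simulations, which gave all groups 1 spread per gene, 21 of 67 changes of 1.5-fold were recovered at 48 hpf and 28 of 67 at 72 hpf. Genes under about 1 CPM, such as slc1a2a and prnpa, rest on few counts.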

Other observations

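All tests of explanations in this part, and all counts over other splits of the libraries, were chosen after the results were seen.

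Genes at or near 0 in a whole group were looked at beyond the rule for named genes. At 48 hpf, 10 genes were expressed in all wild-type libraries and had at most 3 counts over the mutant-labelled ones. They included, besides dap1b, fgfr1bl (620 counts against 0, at least 196-fold lower) and si:dkey-19a16.7 (460 against 0, at least 145-fold lower). Only 2 genes showed the opposite, and 0 and 0 genes showed either at 72 hpf.

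mycn RNA was higher in the mutant-labelled libraries at both ages. A single wrong genotype label is argued against by the ratio of the lowest mutant-labelled to the highest wild-type library, which was 1.77 at the age where it was smaller. Genotype labels exchanged at 1 age only are argued against by the genes changed at both ages, of which 14 of 17 moved in the same direction (exact binomial p = 0.0127). This rests in part on mycn and 3 near neighbours, all moving alike at both ages, and without these 4 the count was 10 of 13 (exact binomial p = 0.0923). The binomial test also treats genes as independent replicates, which they are not. An exchange at both ages remains open. Under the labels as given, ribosomal proteins were lower, with 79 and 78 of 80 negative, which is the direction known for loss of a Myc factor. That list was called by fry (adjusted p = 0.0253 at both ages) but not by camera with an estimated correlation (adjusted p = 0.357 and 0.153). The allele is not described either, so this excludes nothing. A loss of feedback by which the protein could lower its own transcript, and a regulatory variant next to the mutant allele, also remain open and were not tested.

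Genes changed at 72 hpf lay near mycn more often than elsewhere. Nearest genes were chosen by the distance between gene starts in the GRCz12tu table. Among the 100 tested genes nearest to mycn 6 had changed (6%), namely rock2b, henmt1, cep57l1, mettl11b, BX279523.1 and acat2, against 0.499% of 18228 genes on other chromosomes (Fisher's exact p = 1.50e-05). At 72 hpf 0 of 18228 windows of 100 genes on other chromosomes held as many, the highest holding 5. A window was centred on each gene, so windows overlap heavily and are not independent. Runs of changed neighbours as a general feature are thus argued against only weakly. Fisher's tests in this paragraph also treat genes as independent replicates, which they are not. At 48 hpf 10 of the 100 had changed (Fisher's exact p = 6.42e-04), and 47 windows elsewhere (0.258%) held as many, the highest holding 16. For the difference between ages 2 had changed and 1039 windows (5.70%) held as many. On the rest of this chromosome 26, 11 and 10 of 700 genes had changed at 48 hpf, at 72 hpf and for the difference (3.71%, 1.57% and 1.43%). On other chromosomes the shares were 2.86%, 0.499% and 0.400% (Fisher's exact p = 0.204, 0.00137 and 9.56e-04). The excess at 72 hpf was thus largest near mycn but not confined to the 100 nearest genes. A candidate explanation is that variants linked to the mutant allele change the expression of neighbours, with BX279523.1 lower by 4.99 and rock2b higher by 1.65 on the log2 scale; effects of the mutation itself on these genes were not tested. Only 3 of the 57 enterocyte genes lie on this chromosome, and camera at its preset correlation also called the list without them (median -0.44, adjusted p = 8.74e-31). The test with an estimated correlation was not repeated without them. Whether the region acts on gut genes elsewhere was not tested.

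The 10 genes silent in the mutant-labelled 48 hpf libraries form the remaining pattern. Lower depth is argued against, since the summed effective depth of these libraries was 0.948 of the wild-type one. For 3 of the genes, si:dkey-169i5.4, si:dkey-93m18.6 and BX571811.2, loss from the mutant line is argued against, because the mutant-labelled 72 hpf libraries held 175, 25 and 37 counts; for the other 7 it cannot be told apart, since 0 of them passed 3 counts in either genotype at 72 hpf. Other parents for the wild-type 48 hpf embryos may account for these 7: 15 genes stood apart in that group alone, against 3, 0 and 1 in the mutant-labelled 48 hpf, wild-type 72 hpf and mutant-labelled 72 hpf groups. The 15 include 6 of the 7, and 0 of the 3 expressed at 72 hpf. Standing apart meant that all libraries of a group lay more than 2-fold outside all others, with the other groups' means within 1.5-fold. Genes at the floor in the other groups meet this almost by definition, and genes expressed at 72 hpf but silent in 1 group at 48 hpf cannot. The 6 of 7 and 0 of 3 therefore speak neither for nor against other parents. Among the 15 are also mgst2 and tmem176l.3a, besides dap1b and fgfr1bl, so the same doubt holds for these falls. No label gives the clutch, so parents and group cannot be told apart.

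Other splits of the libraries were fitted in the same way. At 48 hpf the real split called 641 genes and the highest of the other 9 splits of the 6 libraries 327. That split set wild-type replicates 1 and 2 with mutant-labelled replicate 3, and at an unadjusted p under 0.05 it gave 3667 genes against 3654 for the real one. At 72 hpf the counts were 117 and 0 (unadjusted 1633 and at most 470), and for the age change 14918 and 0 in wild type (15344 and at most 655) and 14785 and 0 in mutant-labelled libraries (15190 and at most 450). The lists gave 16 against 18 at 48 hpf, where 6 of the 10 splits called as many, and 16 against 15 at 72 hpf. With 10 splits a share under 0.05 cannot be reached for any of these, so none of them excludes chance. For the lists at 48 hpf other splits also reached as many calls, so their number does not set the real split apart. For the difference between ages, 2 of 100 splits called as many as the real 99 genes, so chance is excluded at that level for libraries without any genotype effect. An equal effect at both ages is not tested by these splits, because the others carry the genotype effects in their spread. The other split was the real genotype split with the labels of 1 age reversed, which adds the effects and called 436, and the highest of the remaining groupings called 38. For the 13 lists of the difference, 50 of 100 splits called as many and the highest 18, so chance is not excluded.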
